A study of Capra hircus with 6 samples.

How the data were processed

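The measurement was messenger RNA sequencing of 6 libraries from the goat cell line mGSCs-I-SB, 2 from each of the lines shCON, shUCHL1 and shHSPA8. Per the labels' protocols, cells grew in medium with 10% fetal bovine serum, RNA was taken with a column kit, and 1.3 ug of total RNA went into SMARTER mRNA-seq libraries. Groups and replicate numbers were taken from the sample titles. Reads were handled with Trimmomatic 0.36, per the submitters' processing notes. The aligner, the counting tool, the genome build and the strand setting are not given in the sources used here, and reads that map to more than 1 member of a gene family may have been shared out in a way that is not recorded.

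The authors deposited 1 table with 33229 entries, of which 16599 carry values and 16630 are blank (6587 with NCBI gene IDs and 10043 with other IDs). Blank entries were not used here. Per the file headers, the authors give for each library an FPKM value and a read count. About 1000 genes per library (1014 to 1117) have read counts printed with a decimal fraction of any size, so the deposited read counts are taken to be expected counts, that is estimates, and they were rounded to whole numbers before testing. The deposited FPKM values were used only for transcript length, from the ratio of counts to FPKM. Per the file headers, the authors also give a mean of the expected counts per group, a log2 ratio of each pair of lines and a p-value for it. The test behind those p-values and whether they are adjusted are not given in the sources used here. All 16599 gene IDs with values were found in the RefSeq gene table of assembly ARS1.2, 16597 of them with the same symbol. That table served only for names, and no coordinates are given because the authors' build is not stated. No mitochondrially encoded gene carried values, so that share was not analysed here.

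Total counts ran from 1.57e+07 to 1.64e+07 per library, and the 10 most abundant genes held 6.50% to 8.03% of them. TMM factors ran from 0.966 to 1.04. The main test was edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) after filterByExpr and TMM scaling, with group as the only term and all 6 libraries sharing 1 estimate of the spread. It covered 12665 genes in 3 comparisons, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Genes past that threshold are called changed. The SE of a log2 fold change was approximated as its size divided by the square root of the F statistic. CPM values use the TMM factors.

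Before the data were examined, the test, the named-gene rule, 36 gene lists and the alternatives were fixed. Those lists cover germ cell stages, other cell types of the testis, proteostasis, stress, immunity, proliferation, niche, signalling and metabolism, with some technical sets, and 34 had at least 5 tested members. Older symbols were matched for 20 members. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Of 16, 12 and 7 lists called in shUCHL1, in shHSPA8 and between the knockdown lines, 2, 4 and 1 kept their call with an estimated correlation. Members counted as higher or lower passed the gene test over all genes, and a second count adjusts over the list alone.

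Named genes were chosen by the fixed rule. It took the targeted genes. Per comparison with shCON it took the 8 largest rises and falls among called genes with a symbol other than a LOC identifier, groups that do not overlap and at least 5 CPM on average. Between the knockdown lines it took the 5 highest and 5 lowest. From each called list it took up to 4 members in the direction of the test and up to 2 in the other, and from other lists up to 3 with the lowest p. Of genes called in both lines it took 4 per pattern. Not all genes so chosen are described: 55 of 136 named calls in shUCHL1, 37 of 134 in shHSPA8 and 1 of 18 between the knockdown lines were lost without at least 1 library. For 5 genes so chosen, 3 or fewer counts were summed in a group, and no fold is given for them. A few genes that the rule chose are not reported here.

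The calls were tested on simulated data with the shCON means, the fitted spread and the library sizes, for shUCHL1 against shCON over 12665 genes. The test recovered 24 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 64 of 66 changed 4-fold. It also called 17 of 12425 unchanged genes. Set beside the genes recovered, these 17 false calls were a larger share of all calls than the adjusted p threshold allows for. For simulated shHSPA8 against shCON, where no gene had been changed, 3 genes were called. A raised list was called, and 0 of 30 unchanged lists were. So differences under 1.5-fold are mostly not detectable with 2 libraries per line. Overlap between the comparisons with shCON was set beside 40 simulated sets of unchanged lines and beside independent lists.

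The main test was set beside DESeq2 1.42.0, limma-voom, DESeq2 size factors, library size alone, no low-count filter, a filter of 1 CPM in 2 libraries, only the 2 groups compared, replicate number as a block, each library left out, a minimum absolute log2 fold change of 1 and an adjusted p of 0.01. A length correction and voom weights per group were chosen after seeing the data. The length correction removes each library's loess trend of log2 CPM on transcript length (span 0.5), since the libraries of a line differed along length. Across genes, Spearman's rho of that difference with length was 0.465 between the shCON libraries, -0.466 between the shHSPA8 libraries and 0.257 between the shUCHL1 libraries, against 0.167 for shUCHL1 against shCON and -0.007 for shHSPA8 against shCON. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.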

Results

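RNA was sequenced from mGSCs-I-SB, a goat (Capra hircus) cell line that the labels describe as spermatogonial stem cells, the self-renewing germ cells of the testis. The 6 libraries came from 3 lines carrying short hairpin RNAs, with 2 libraries per line. The lines carried control hairpin RNA (shCON), hairpin RNA against UCHL1 (shUCHL1) or hairpin RNA against HSPA8 (shHSPA8). The labels do not say how many hairpins were used per gene. UCHL1 is a ubiquitin C-terminal hydrolase long used as a marker of undifferentiated spermatogonia, and HSPA8 is the constitutive HSP70 chaperone of the cytosol. The series title sets the first gene against the second, and the design compares the 3 lines. Total counts lay between 1.57e+07 and 1.64e+07 per library, and 12665 genes entered the tests. Levels are CPM, read counts scaled to a common library size with TMM factors, as mean ± SD with n = 2 libraries per line, and each log2 fold change is followed by its standard error (SE). Nothing in the labels says that the libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. That spread differed between lines: replicate counts departed from each other by 21.7 times the chi-square expected of sampling noise per degree of freedom in shCON, 11.6 times in shHSPA8 and 2.32 times in shUCHL1. In every line the departure exceeded sampling noise, so no library was counted as a copy of another.

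The targeted transcript was lower in each knockdown line. UCHL1 (gene ID 102178714) stood at 428 ± 32.3 CPM in shCON, 96.0 ± 2.36 CPM in shUCHL1 and 360 ± 36.5 CPM in shHSPA8. In shUCHL1 it was 4.46-fold lower than in shCON (log2 fold change -2.16, SE 0.11), with an adjusted p of 1.1e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. HSPA8 (gene ID 102182240) stood at 4064 ± 67.9 CPM in shCON, 5298 ± 65.4 CPM in shUCHL1 and 2579 ± 73.4 CPM in shHSPA8. It was 1.58-fold lower in shHSPA8 than in shCON (log2 fold change -0.66, SE 0.07), with an adjusted p of 0.0013 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

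The title relates the genes to each other, so each was also read in the line of the other. HSPA8 rose 1.30-fold in shUCHL1 (log2 fold change 0.38, SE 0.07), with an adjusted p of 0.0129 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both shUCHL1 libraries lay above both shCON libraries. By the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.150 without shUCHL1 replicate 1 and 0.175 without shUCHL1 replicate 2, with the log2 fold change at 0.38 and 0.35. UCHL1 in shHSPA8 had a log2 fold change of -0.25 (SE 0.10) that did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.151). After a length correction, the adjusted p of that difference was 0.018 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with a log2 fold change of -0.28, and over all alternatives it ran from 0.018 to 0.508. Between the knockdown lines, HSPA8 was 2.05-fold higher in shUCHL1 than in shHSPA8 (log2 fold change 1.04, SE 0.07) and UCHL1 was 3.75-fold lower (-1.91, SE 0.11).

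**Figure D1:**
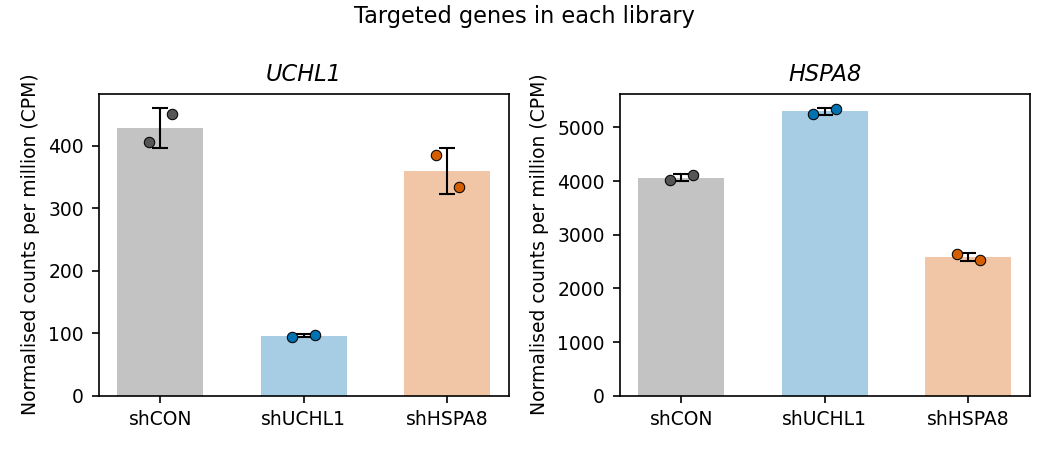
CPM of UCHL1 and HSPA8 in the 3 lines; bars are means, error bars are SD and points are the 2 libraries of each line. UCHL1 is lowest in shUCHL1 (96.0 CPM), and HSPA8 is lowest in shHSPA8 (2579 CPM) and highest in shUCHL1 (5298 CPM).

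The first comparison asks what went with the fall of UCHL1 transcripts. Against shCON, shUCHL1 cells carried more transcripts of inflammatory genes and fewer of cholesterol synthesis enzymes. Among inflammatory cytokines, chemokines and NF-kB targets, 21 of 37 tested genes rose and 2 fell, and among enzymes of cholesterol and fatty acid synthesis 25 of 36 fell and none rose. Stress-response genes (20 of 43 up and 1 down) and hypoxia-inducible genes (11 of 25 up) rose as well, in lists that lost their call with an estimated correlation (adjusted p = 0.197 for both). CNN1, the actin-binding protein calponin of smooth muscle, fell 14.7-fold, from 12.5 ± 2.43 to 0.850 ± 0.354 CPM. FLT1, a receptor for vascular endothelial growth factor, rose 8.58-fold, from 6.39 ± 0.461 to 54.8 ± 0.730 CPM. In all, 1987 of 12665 genes changed, 1082 up and 905 down, and 592 of the higher and 202 of the lower genes differed by at least 2-fold. The inflammatory and cholesterol lists moved the same way in shHSPA8. With no second control line, a shCON line that itself departed cannot be told apart from a response to the hairpins for them.

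Of the genes with the largest rises in shUCHL1, IGSF3 rose 10.3-fold (log2 fold change 3.36, SE 0.16) and SEMA3C, a secreted semaphorin, 10.1-fold (3.34, SE 0.26). MEDAG rose 9.86-fold (3.30, SE 0.16), FAM49A 9.20-fold (3.20, SE 0.14) and JAM2, a junctional adhesion molecule, 8.86-fold (3.15, SE 0.18). KCNMA1, a calcium-activated potassium channel, rose 8.27-fold (3.05, SE 0.20) and TLR2, a receptor for bacterial lipoproteins, 8.18-fold (3.03, SE 0.16). Among the falls, IGFBP2, a binding protein of insulin-like growth factors, fell 15.7-fold (log2 fold change -3.97, SE 0.20) and the epithelial keratin KRT8 15.1-fold (-3.92, SE 0.22). The channel protein PANX1 fell 8.85-fold (-3.15, SE 0.27), the fatty acyl-CoA reductase FAR2 7.67-fold (-2.94, SE 0.19) and SBSPON 7.29-fold (-2.87, SE 0.23). PXDN, the peroxidase that cross-links basement membrane collagen, had 5 counts over both shUCHL1 libraries against 337 in shCON, a fitted fall of 65.9-fold (-6.04, SE 0.39). Adjusted p for the genes of this paragraph ran from 8.34e-05 for FAM49A to 6.41e-04 for PANX1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

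Gene lists fixed in advance gave the groups, tested with camera at its preset correlation. In shUCHL1 the inflammatory list had a median log2 fold change of 0.90, with 27 members up and 2 down when adjusted over the list alone (camera adjusted p = 4.0e-23, and adjusted p = 0.04998 with an estimated correlation, just under the threshold). PTGS2, the inducible prostaglandin synthase, rose by 2.72 (SE 0.12), complement C3 by 2.70 (SE 0.09) and IL1B by 2.30 (SE 0.28) on the log2 scale. IL18 (-0.44, SE 0.12) and CSF1 (-0.34, SE 0.08) fell. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, IL18 lost its call without shCON replicate 2, either shUCHL1 library or shHSPA8 replicate 1 (adjusted p from 0.0503 to 0.323). CSF1 lost its call in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without each library other than shCON replicate 1 (adjusted p from 0.0521 to 0.255). In the unfolded protein and integrated stress response list, 20 of 43 genes rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 2.5e-12, and adjusted p = 0.197 with an estimated correlation). VLDLR rose by 1.68 (SE 0.12), CHAC1, which degrades glutathione, by 1.55 (SE 0.20) and the stress sensor SESN2 by 1.34 (SE 0.17). Of the hypoxia-inducible genes, 11 of 25 rose and none fell (16 and 0 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 3.3e-09, and adjusted p = 0.197 with an estimated correlation). They included STC1 (2.29, SE 0.19), the carbonic anhydrase CA12 (2.06, SE 0.09) and the prolyl hydroxylase EGLN3 (1.20, SE 0.16).

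Matrix metalloproteinases and their inhibitors shifted upward in shUCHL1, with 13 of 33 genes up and 4 down (14 and 4 adjusted over the list alone) and a median log2 fold change of 0.33 (camera adjusted p = 0.00308, and adjusted p = 0.241 with an estimated correlation). MMP1 rose by 3.70 (SE 0.26), MMP12 by 2.68 (SE 0.36) and ADAMTS5 by 2.22 (SE 0.32), and MMP16 rose 5.64-fold. ADAMTS9 fell (-2.20, SE 0.19). Interferon-stimulated genes had 12 of 35 up and 1 down (13 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 0.00656, and adjusted p = 0.232 with an estimated correlation), among them RSAD2 (3.30, SE 0.53), which rested on 7 counts over both shCON libraries. WNT pathway genes had 12 of 35 up and 3 down (15 and 6 adjusted over the list alone; median 0.29, camera adjusted p = 0.0232, and adjusted p = 0.245 with an estimated correlation), with SFRP4 up (2.24, SE 0.16) and TCF7L1 down (-2.16, SE 0.20). Of the heat shock chaperones, 8 of 47 rose and none fell (12 and 1 adjusted over the list alone; median 0.10, camera adjusted p = 0.0261, and adjusted p = 0.433 with an estimated correlation), with HSPA12A (2.40, SE 0.31), HSPA6 (2.15, SE 0.18) and DNAJB9 (0.93, SE 0.11) up. Growth factors and receptors of the stem cell niche had 15 of 37 up and 6 down (18 and 8 adjusted over the list alone; median 0.33, camera adjusted p = 0.0261, and adjusted p = 0.473 with an estimated correlation). IGFBP3 rose by 3.02 (SE 0.17), and PDGFB (-2.56, SE 0.29) and the activin subunit INHBA (-1.55, SE 0.10) fell. The niche list was not called without shCON replicate 2 (camera adjusted p = 0.150), and after the length correction the camera adjusted p was 0.0506 for both the niche and the WNT list.

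On the lower side in shUCHL1, the cholesterol and fatty acid list had 30 members down and none up when adjusted over the list alone, with a median log2 fold change of -0.54 (camera adjusted p = 4.2e-15, and adjusted p = 0.04998 with an estimated correlation, just under the threshold). FASN, the fatty acid synthase, fell 2.12-fold (-1.08, SE 0.08). ACSS2 (-0.94, SE 0.16) and the elongase ELOVL6 (-0.93, SE 0.14) fell as well. Their adjusted p was 0.101 for ACSS2 without shUCHL1 replicate 1 and 0.0639 for ELOVL6 without shUCHL1 replicate 2, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Markers of peritubular myoid cells and fibroblasts, the contractile and matrix cells around the seminiferous tubule, had 9 of 23 down and 4 up (10 and 5 adjusted over the list alone). Their mean log2 fold change was -0.58 and the list test pointed down, while the median was 0.08 (camera adjusted p = 6.1e-04, and adjusted p = 0.473 with an estimated correlation). The members that fell most were contractile or cytoskeletal: CNN1 (-3.88, SE 0.30), the intermediate filament gene DES (-3.85, SE 0.29), the actin nucleator LMOD1 (-2.07, SE 0.13) and smooth-muscle actin ACTA2 (-1.58, SE 0.12). The matrix genes DCN (1.07, SE 0.08) and IGFBP5 (1.02, SE 0.09) rose. Integrins and adhesion genes had 10 of 35 down and 4 up (12 and 6 adjusted over the list alone; median -0.22, camera adjusted p = 0.0294, and adjusted p = 0.473 with an estimated correlation), with ITGA2 (-1.37, SE 0.20) and L1CAM (-1.31, SE 0.10) down and CDH6 up 2.84-fold.

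The other lists called in shUCHL1 moved by little. G2/M and mitosis genes had 7 of 61 down and none up (7 and 0 adjusted over the list alone; median -0.09, camera adjusted p = 0.0261, and adjusted p = 0.473 with an estimated correlation), and without shCON replicate 1 the camera adjusted p was 0.185. Of 74 cytosolic ribosomal proteins 4 were down and none up (1 and 0 adjusted over the list alone; median -0.13, camera adjusted p = 0.00888, and adjusted p = 0.865 with an estimated correlation). Without shCON replicate 2 their camera adjusted p was 0.956 and their median 0.02. Respiratory chain subunits had 1 of 57 down and none up (1 and 0 adjusted over the list alone; median -0.12, camera adjusted p = 0.0261, and adjusted p = 0.865 with an estimated correlation). Their camera adjusted p was 0.678 without shCON replicate 2 and 0.0566 without shUCHL1 replicate 1. Proteasome subunits had 2 of 33 down and none up (2 and 0 adjusted over the list alone; median -0.09, camera adjusted p = 0.0481, and adjusted p = 0.779 with an estimated correlation), with an camera adjusted p of 0.180 without shCON replicate 2 and 0.0965 without shUCHL1 replicate 1. After the length correction the camera adjusted p was 0.330 for the ribosomal, 0.380 for the respiratory and 0.216 for the proteasome list. Only 5 macrophage and leukocyte markers were tested, of which 2 fell, the actin bundler LCP1 by 1.84 on the log2 scale (SE 0.08) and CORO1A by 0.94 (SE 0.24). That list had a median of 0.20 but a mean of -0.27 and a downward test (camera adjusted p = 0.0261, and adjusted p = 0.473 with an estimated correlation). Adjusted over the list alone, 1 of the markers was up and 2 were down. It was not called without any 1 library, with camera adjusted p of 0.103 and 0.182 without shCON replicate 1 and 2, 0.300 and 0.205 without shUCHL1 replicate 1 and 2, and 0.237 and 0.127 without shHSPA8 replicate 1 and 2. CORO1A lost its call without each library other than shCON replicate 1 (adjusted p from 0.0599 to 0.280 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

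The tested markers of spermatogonial stem cells and progenitors did not move together in shUCHL1. Of 44 listed, 29 carried values and 19 were tested, 12 of them also in another list. The untested members had no values or too few counts for the low-count filter. With most of the list untested, it cannot settle germ cell identity. Among markers of other cell types, 23 of 25 were tested for myoid cells and fibroblasts, 15 of 25 for Sertoli cells and 9 of 18 for Leydig cells. Of the 19 stem cell and progenitor markers tested, 8 rose and 4 fell (9 and 5 adjusted over the list alone, median 0.16). Their list was not called (camera adjusted p = 0.878). The targeted gene is itself a member. KLF4, a pluripotency transcription factor, rose by 1.47 (SE 0.10), and the surface marker THY1 fell by 1.28 on the log2 scale (SE 0.12). Collagens and other matrix genes had 13 of 53 up and 11 down (18 and 15 adjusted over the list alone; median 0.03, and -0.07 after the length correction) and were not called (camera adjusted p = 0.987). Neither were markers of Sertoli cells (4 of 15 up and 5 down, camera adjusted p = 0.966), Leydig cells (none of 9 up and 2 down, camera adjusted p = 0.216) or endothelium (2 of 9 up and 1 down, camera adjusted p = 0.334). Over the 18 lists not called in shUCHL1, the camera adjusted p ran from 0.110 to 0.987.

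Leaving out a shUCHL1 library left fewer changed genes in this comparison: 528 without replicate 1 and 530 without replicate 2, with the remaining library assumed to vary like those of the other lines. Scaling by library size alone gave 1368 higher among 2009 changed genes (68.1%), against 1082 of 1987 with the TMM scaling used here. The majority was lower with DESeq2 (744 of 1593 higher, 46.7%), without shCON replicate 1 (1153 of 2615, 44.1%) and with voom weights per group, chosen after seeing the data (829 of 1690, 49.1%), so the split in shUCHL1 has no settled direction.

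The second comparison asks what went with the partial fall of HSPA8 transcripts. In shHSPA8 inflammatory genes rose above shCON, and matrix genes and metalloproteinases rose with them, while cholesterol synthesis enzymes fell. Of the 37 inflammatory genes, 26 rose and 1 fell, and of 53 collagens and matrix genes 34 rose and 5 fell. PTGS2 rose 14.6-fold, from 15.9 ± 1.04 to 233 ± 27.6 CPM, and the matrix glycoprotein TNC (tenascin C) 8.86-fold, from 64.0 ± 0.868 to 567 ± 14.6 CPM. PPL, the plakin periplakin, fell 13.8-fold, from 43.0 ± 4.34 to 3.10 ± 0.00403 CPM. In all, 1859 of 12665 genes changed, 1097 up and 762 down, of which 579 and 187 differed by at least 2-fold. The inflammatory and cholesterol changes ran the same way in shUCHL1, so the limit from a single control line holds for them here too.

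Among the largest rises in shHSPA8, COL18A1, a basement membrane collagen, rose 27.9-fold (log2 fold change 4.80, SE 0.23) and the potassium channel KCNJ15 18.5-fold (4.21, SE 0.20). The COL18A1 fold rested on 15 counts over both shCON libraries. MEDAG rose 13.2-fold (3.72, SE 0.16), the matricellular gene SMOC1 12.6-fold (3.66, SE 0.15) and JAKMIP2 10.5-fold (3.39, SE 0.19). CSF3, the granulocyte colony-stimulating factor, had 319 counts over both shHSPA8 libraries against 7 in shCON, a fitted rise of 5.50 on the log2 scale (SE 0.37). Among the falls, KANK4 fell 9.02-fold (-3.17, SE 0.23), NIPAL4 8.39-fold (-3.07, SE 0.20) and ALDH1A3, which makes retinoic acid, 8.13-fold (-3.02, SE 0.11). EMCN, an endothelial sialomucin, fell 7.02-fold (-2.81, SE 0.13) and CRABP2, which carries retinoic acid to its receptor, 5.21-fold (-2.38, SE 0.16). FAM110C fell 5.16-fold (-2.37, SE 0.15) and the vasoconstrictor peptide gene EDN1 4.87-fold (-2.29, SE 0.13). Adjusted p for the genes of this paragraph ran from 2.29e-05 for ALDH1A3 to 2.38e-04 for KANK4 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

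The inflammatory list had a median log2 fold change of 1.17 in shHSPA8, with 29 up and 1 down adjusted over the list alone (camera adjusted p = 2.2e-45, and adjusted p = 0.0261 with an estimated correlation). PTGS2 (3.87, SE 0.12) and IL1B (3.06, SE 0.26) rose. IL18 fell by 0.74 on the log2 scale (SE 0.12), with an adjusted p of 0.0540 without shHSPA8 replicate 2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Collagens and matrix genes had a median of 0.54, with 38 up and 5 down adjusted over the list alone (camera adjusted p = 5.6e-18, and adjusted p = 0.0261 with an estimated correlation). TNC rose by 3.15 (SE 0.09), the proteoglycan VCAN by 2.53 (SE 0.24) and the laminin chain LAMA4 by 1.69 (SE 0.11), and the fibulin FBLN1 fell (-1.45, SE 0.11). Of 33 matrix metalloproteinases and inhibitors 14 rose and none fell (20 and 0 adjusted over the list alone; median 0.47, camera adjusted p = 3.1e-13, and adjusted p = 0.0362 with an estimated correlation). MMP1 rose by 4.09 (SE 0.25), MMP3 by 2.75 (SE 0.12), ADAMTS5 by 2.56 (SE 0.32) and MMP12 by 2.28 (SE 0.38). Cholesterol and fatty acid synthesis had 25 of 36 down and none up (31 and 0 adjusted over the list alone; median -0.58, camera adjusted p = 6.5e-16, and adjusted p = 0.0261 with an estimated correlation). ACSS2 (-1.54, SE 0.16), HSD17B7 (-1.30, SE 0.17) and INSIG1 (-1.21, SE 0.11), which retains the sterol sensor in the endoplasmic reticulum, were among them. These 4 lists were the ones that kept their call with an estimated correlation.

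Immediate early genes and feedback regulators of MAPK signalling had 12 of 39 up and 5 down in shHSPA8 (12 and 5 adjusted over the list alone; median 0.18, camera adjusted p = 0.001004, and adjusted p = 0.235 with an estimated correlation). The ligand HBEGF (1.98, SE 0.17) and the transcription factors EGR1 (1.95, SE 0.09), NR4A1 (1.76, SE 0.15) and NR4A3 (1.76, SE 0.20) rose. ATF3 (-0.88, SE 0.14) and KLF4 (-0.57, SE 0.11) fell, with adjusted p of 0.0542 and 0.0890 without shHSPA8 replicate 2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without shHSPA8 replicate 1, KLF4 had an adjusted p of 0.0739 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Niche growth factors and receptors had 16 of 37 up and 5 down (16 and 9 adjusted over the list alone; median 0.17, camera adjusted p = 9.4e-05, and adjusted p = 0.312 with an estimated correlation). NRG1 (3.28, SE 0.40), FGF10 (2.72, SE 0.29) and IGFBP3 (2.28, SE 0.18) rose, and PDGFB (-2.76, SE 0.30) and the chemokine receptor ACKR3 (-0.94, SE 0.10) fell. Hypoxia-inducible genes had 8 of 25 up and none down (8 and 2 adjusted over the list alone; median 0.10, camera adjusted p = 2.1e-04, and adjusted p = 0.318 with an estimated correlation), with CA12 (2.51, SE 0.09), STC1 (2.10, SE 0.19) and the glucose transporter SLC2A1 (1.45, SE 0.08) among them. Lysosomal hydrolases and membrane proteins had 8 of 41 up and none down (8 and 0 adjusted over the list alone; median 0.20, camera adjusted p = 0.00246, and adjusted p = 0.482 with an estimated correlation). They included the cathepsins CTSK (2.03, SE 0.14), CTSL (1.60, SE 0.20) and CTSH (0.94, SE 0.10) and the sterol carrier NPC2 (1.17, SE 0.10).

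Of the unfolded protein and integrated stress response genes, 12 of 43 rose and 1 fell in shHSPA8 (12 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.0148, and adjusted p = 0.482 with an estimated correlation). VLDLR (1.41, SE 0.12), the serine synthesis enzyme PSAT1 (1.10, SE 0.09) and NUPR1 (1.09, SE 0.14) rose. Heat shock chaperones other than the targeted gene had 10 of 47 up and 1 down (12 and 1 adjusted over the list alone; median 0.15, camera adjusted p = 0.0271, and adjusted p = 0.401 with an estimated correlation). HSPA6 (1.59, SE 0.19) and HSP70.1 (1.05, SE 0.11), both inducible members of the HSP70 family, and the co-chaperone DNAJA1 (0.64, SE 0.08) rose. The co-chaperone BAG2 fell by 0.57 on the log2 scale (SE 0.10). Its adjusted p was 0.0605 and 0.0787 without shHSPA8 replicate 1 and 2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The chaperone list was not called without shHSPA8 replicate 1 (camera adjusted p = 0.0719). Myoid and fibroblast markers had 8 of 23 up and 3 down (9 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.0271, and adjusted p = 0.665 with an estimated correlation). IGFBP5 (1.02, SE 0.09), COL3A1 (1.01, SE 0.08), FAP (1.01, SE 0.11) and PDPN (0.92, SE 0.07) rose, and FBLN1 (-1.45, SE 0.11) and S100A4 (-0.85, SE 0.13) fell. The myoid list had adjusted p of 0.264 without shCON replicate 1, 0.0618 and 0.0632 without shUCHL1 replicate 1 and 2, 0.138 without shHSPA8 replicate 1 and 0.123 after the length correction, all from camera. G2/M and mitosis genes had 6 of 61 down and none up (1 and 0 adjusted over the list alone; median -0.16, camera adjusted p = 0.00338, and adjusted p = 0.478 with an estimated correlation), with the phosphatase CDC25B down (-0.62, SE 0.09).

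The 19 tested stem cell and progenitor markers, of 44 listed, were not called in shHSPA8 (camera adjusted p = 0.662). Of them 2 were up and 1 down, with the same numbers adjusted over the list alone (median -0.11, mean 0.27). FOXO1 (0.84, SE 0.10) and ID4 (1.85, SE 0.24), both transcription factors of undifferentiated spermatogonia, rose, and KLF4 fell (-0.57, SE 0.11). KLF4 lost its call without shHSPA8 replicate 1 (adjusted p = 0.0739) or replicate 2 (adjusted p = 0.0890) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over the 22 lists not called in this comparison the camera adjusted p ran from 0.0549 to 0.851. Fewer genes were called without a knockdown library: 946 and 920 without shHSPA8 replicate 1 and 2, and 1108 without either shUCHL1 library. The lone shHSPA8 library was assumed to vary like those of the other lines. Fitting only the shHSPA8 and shCON libraries, without the more alike shUCHL1 libraries in the spread, gave 1104 changed genes.

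**Figure D2:**
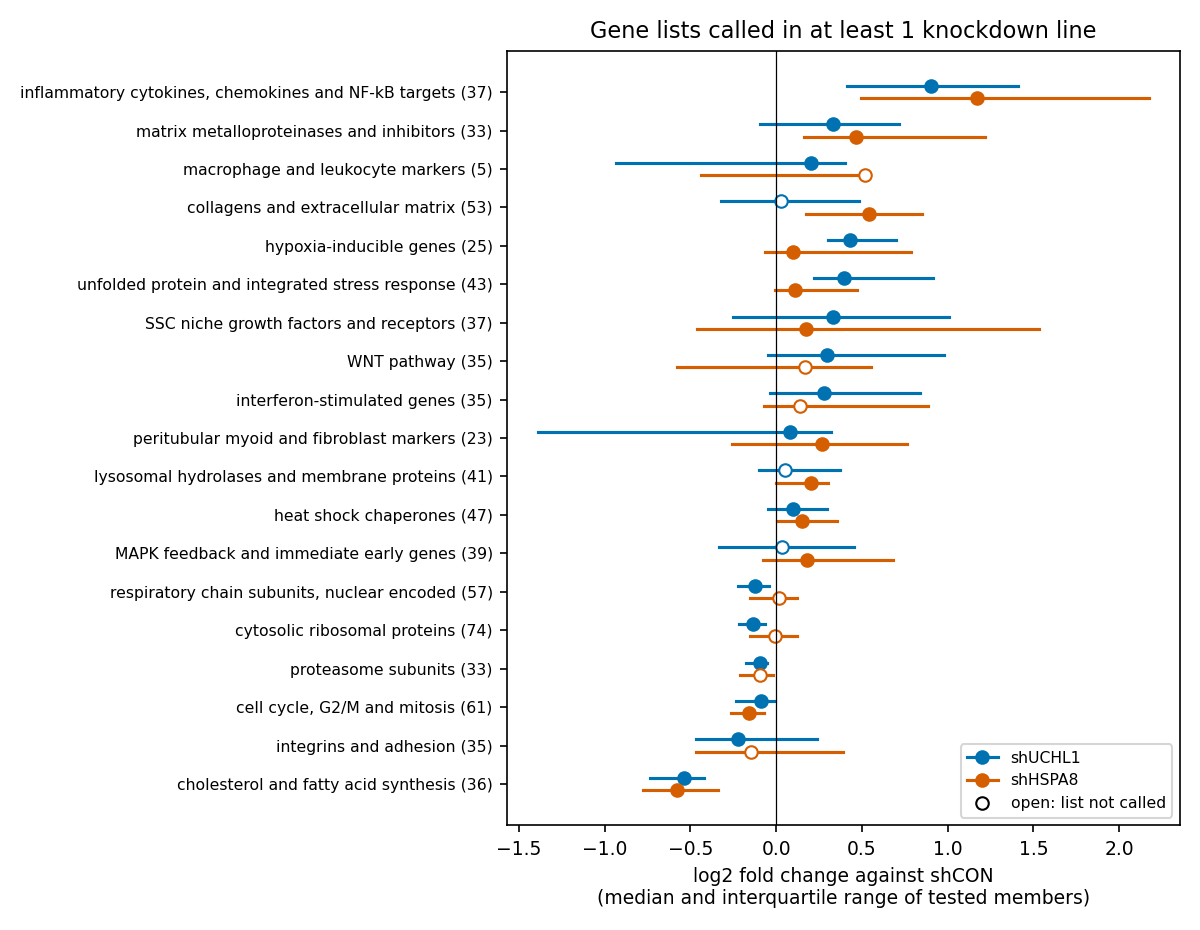
Median log2 fold change (points) and interquartile range (lines) against shCON of the tested members of each gene list called in at least 1 knockdown line, with the number of tested members in brackets; filled points mark called lists. The inflammatory list lies highest (medians 0.90 and 1.17) and cholesterol and fatty acid synthesis lowest (-0.54 and -0.58), while the myoid and macrophage lists in shUCHL1 have medians above 0 but means below 0 and a downward test.

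The direct comparison of the knockdown lines asks where their responses differ and involves no control library in its fold changes. Matrix genes were lower in shUCHL1 than in shHSPA8: of 53 collagens and matrix genes, 30 were lower and 1 was higher. Immediate early genes (14 of 39 lower and 3 higher) and stress-response genes (13 of 43 higher and 1 lower) differed in lists that lost their call with an estimated correlation (adjusted p = 0.273 and 0.391). TNC stood at 60.0 ± 2.38 CPM in shUCHL1 against 567 ± 14.6 CPM in shHSPA8, a 9.45-fold difference. Contractile CNN1 stood at 0.850 ± 0.354 against 18.6 ± 3.14 CPM, and PPL at 41.3 ± 0.307 against 3.10 ± 0.00403 CPM. In all, 1843 of 12665 genes differed, 785 higher and 1058 lower in shUCHL1, with 290 and 291 at least 2-fold apart.

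Among the genes highest in shUCHL1 against shHSPA8 were PPL (log2 fold change 3.73, SE 0.14), the signalling ligand WNT4 (2.89, SE 0.18) and PPP1R3G, a glycogen-targeting phosphatase subunit (2.29, SE 0.19). SMOC2 (2.27, SE 0.20) and C23H6orf132 (2.26, SE 0.12) followed. Among the lowest were PXDN (-6.91, SE 0.36, with 5 counts in shUCHL1 against 599), CNN1 (-4.45, SE 0.30), MXRA8 (-3.91, SE 0.17), CSF3 (-3.74, SE 0.29) and FOLH1B (-3.32, SE 0.29). Collagens and matrix genes had a median of -0.45, with 33 lower and 3 higher adjusted over the list alone (camera adjusted p = 2.7e-21, and adjusted p = 0.0418 with an estimated correlation). TNC (-3.24, SE 0.09), VCAN (-1.21, SE 0.23), LAMA4 (-1.18, SE 0.11) and COL18A1 (-1.09, SE 0.15) were lower in shUCHL1. These list members, like those of the next lists, had been named for the comparisons with shCON. Of the myoid and fibroblast markers 13 of 23 were lower and 2 higher (15 and 2 adjusted over the list alone; median -0.66, camera adjusted p = 8.5e-11, and adjusted p = 0.391 with an estimated correlation), with CNN1, DES (-4.01, SE 0.29), LMOD1 (-1.24, SE 0.14) and ACTA2 (-1.17, SE 0.12) lower. Inflammatory genes had 14 of 37 lower and 4 higher (16 and 4 adjusted over the list alone; median -0.14, camera adjusted p = 4.5e-07, and adjusted p = 0.235 with an estimated correlation), with PTGS2 lower (-1.15, SE 0.11) and C3 higher (0.98, SE 0.08). Metalloproteinases and inhibitors had 10 of 33 lower and 2 higher (12 and 4 adjusted over the list alone; median -0.33, camera adjusted p = 1.2e-05, and adjusted p = 0.235 with an estimated correlation), with MMP3 lower (-1.23, SE 0.10). Immediate early and MAPK feedback genes had 14 of 39 lower and 3 higher (17 and 4 adjusted over the list alone; median -0.21, camera adjusted p = 7.3e-04, and adjusted p = 0.273 with an estimated correlation), with EGR1 (-2.30, SE 0.10) and NR4A1 (-2.14, SE 0.15) lower.

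Of 43 unfolded protein and integrated stress response genes, 13 were higher in shUCHL1 than in shHSPA8 and 1 was lower (14 and 2 adjusted over the list alone; median 0.20, camera adjusted p = 4.1e-05, and adjusted p = 0.391 with an estimated correlation). CHAC1 (1.42, SE 0.20), ATF3 (1.34, SE 0.14) and SESN2 (1.09, SE 0.16) were higher. Of 25 p53 target genes 5 were higher and 3 lower (9 and 5 adjusted over the list alone; median 0.29, camera adjusted p = 0.0416, and adjusted p = 0.540 with an estimated correlation), SESN2 among the higher. That list was not called without shUCHL1 replicate 2 (camera adjusted p = 0.104), shHSPA8 replicate 1 (camera adjusted p = 0.0567) or shHSPA8 replicate 2 (camera adjusted p = 0.0673). Stem cell markers (4 of 19 higher and 4 lower, camera adjusted p = 0.802) and cholesterol synthesis (2 of 36 higher and 3 lower, camera adjusted p = 0.638) were among the 27 lists not called, whose camera adjusted p ran from 0.0769 to 0.928. The count of differing genes depended on the libraries kept. It was lower without any 1 library of the knockdown lines. Leaving 1 out leaves its line with 1 library and weakens the test, so no single library is shown to carry the calls. Without either shCON library the count was higher, the control entering through the shared estimate of the spread. Fitting only the knockdown lines gave 3116. Scaling by library size alone raised the median log2 fold change of all tested genes by 0.10 and gave 1339 higher among 2079 differing genes (64.4%), against 785 of 1843 here, so directions in this comparison are relative to the TMM scaling.

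**Figure D3:**
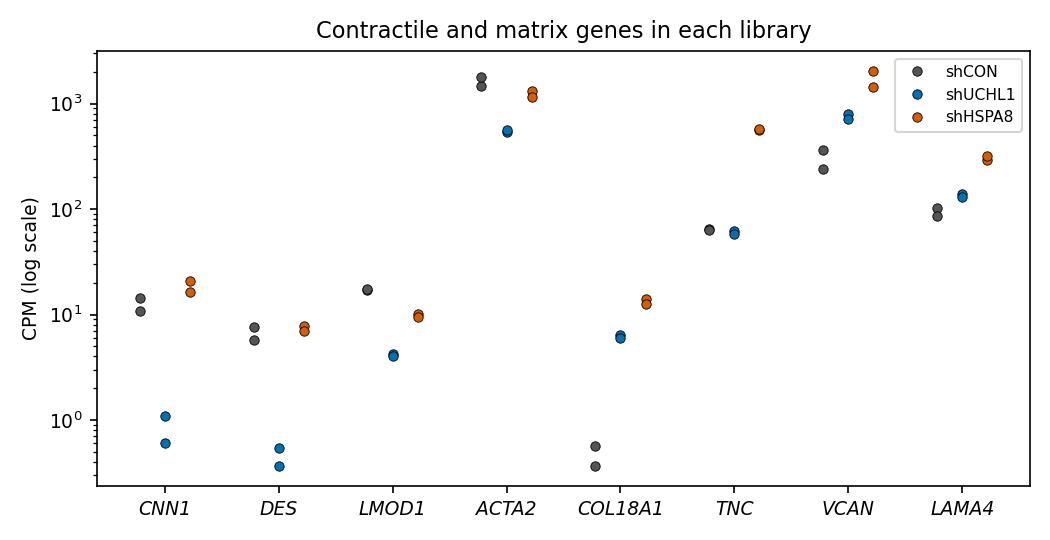
CPM on a log10 axis of contractile genes (CNN1, DES, LMOD1, ACTA2) and matrix genes (COL18A1, TNC, VCAN, LAMA4) in the 3 lines, where points are libraries. The contractile genes are lowest in shUCHL1 and the matrix genes highest in shHSPA8.

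The responses to the hairpins were then set side by side, since the title sets the targeted genes against each other. Of the genes changed against shCON, 887 changed in both knockdown lines, 851 in the same direction and 36 in opposite directions. MEDAG (log2 fold change 3.30 in shUCHL1 and 3.72 in shHSPA8), TLR2 (3.03 and 3.04), KIAA1324L (2.83 and 2.97) and PTGS2 (2.72 and 3.87) rose in both, with SE of 0.12 to 0.19. NIPAL4 (-2.71 and -3.07), EMCN (-2.52 and -2.81), EDN1 (-2.25 and -2.29) and the GABA receptor subunit gene GABRA4 (-2.40 and -2.23) fell in both, with SE of 0.13 to 0.20. WNT4 (1.20 and -1.69), C23H6orf132 (1.23 and -1.04) and KLF4 (1.47 and -0.57) rose in shUCHL1 and fell in shHSPA8, with SE of 0.10 to 0.19. VGF, a neuropeptide precursor (-1.61 and 0.89), the myosin light chain kinase MYLK (-0.998 and 0.57) and PXDN (-6.04 and 0.87) fell in shUCHL1 and rose in shHSPA8, with SE of 0.09 to 0.39. DCHS1 (0.43 and -0.40) and COL11A1 (-0.96 and 0.65) were called in opposite directions as well. Some of these opposite calls were lost with 1 library left out, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each such fit leaves a line with 1 library, which weakens the test. In shHSPA8, KLF4 (adjusted p of 0.0739 and 0.0890) and PXDN (0.0911 and 0.0884) lost their calls without shHSPA8 replicate 1 and 2, and MYLK (0.0628) without replicate 2. COL11A1 lost its call in shHSPA8 without shCON replicate 2, either shUCHL1 library or shHSPA8 replicate 2 (0.0529 to 0.138), and DCHS1 without each library other than shCON replicate 1 (0.0575 to 0.173). In shUCHL1, COL11A1 lost its call without shUCHL1 replicate 2 (0.0607) and DCHS1 without shUCHL1 replicate 1 and 2 (0.219 and 0.204).

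Independent lists of these sizes would share 148 genes in the same direction and 143 in opposite directions. The 851 shared calls were 532 higher in both (93.7 for independent lists) and 319 lower in both (54.5 for independent lists). Of the 36 opposite calls, 12 were up in shUCHL1 and down in shHSPA8 (65.1 for independent lists) and 24 the reverse (78.4 for independent lists). Of the 851, 220 (25.9%) also differed between the knockdown lines. After the length correction, chosen after seeing the data, there were 1217 calls in the same direction and 101 in opposite directions. Both comparisons use the same shCON libraries, so chance values of shCON push their fold changes the same way. In 40 simulated sets of unchanged lines against shared controls, the mean correlation of log2 fold changes across genes was 0.495, against 0.603 observed (Spearman's rho 0.466), where genes are not independent replicates. The share of genes with the same sign averaged 66.5% in the simulation against 64.9% observed, and at most 1 gene was called in both. The covariance was 0.247 observed against 0.0240 simulated (highest 0.0274), a difference of 0.223. The simulation drew genes independently and gave every line the same spread, while the shCON libraries varied most. Their own spread gives an error covariance of 0.0364, above every simulated value. The simulation thus understates what shared controls can give. The controls were not split between the comparisons, which would leave 1 control library in each. Part of the excess of shared calls may therefore come from the shared controls. The 851 genes became 314 and 313 without shUCHL1 replicate 1 and 2 and 523 and 500 without shHSPA8 replicate 1 and 2. The 36 became 8 and 9 without shUCHL1 replicate 1 and 2, and 18 and 16 without shHSPA8 replicate 1 and 2.

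**Figure D4:**
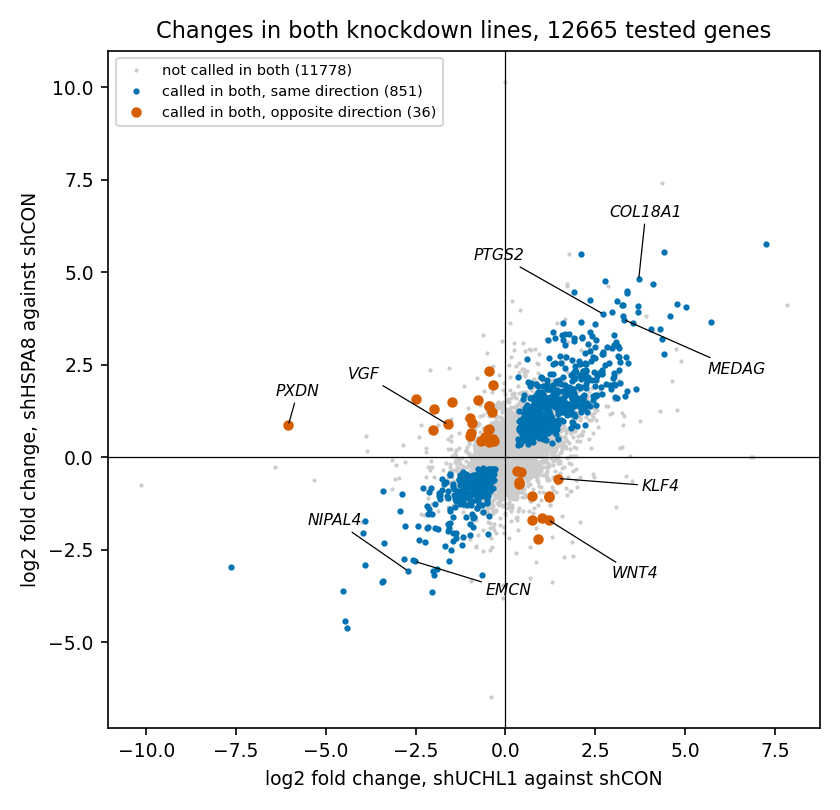
Log2 fold change of each tested gene in shUCHL1 (x axis) and shHSPA8 (y axis) against shCON; blue points are the 851 genes called in both lines in the same direction, orange points the 36 called in opposite directions and grey points all others. Most genes called in both lie at the upper right and lower left, and WNT4, KLF4, PXDN and VGF lie at the upper left or lower right.

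The authors' deposited table gives a log2 ratio and a p-value for each pair of lines. In the authors' deposited table UCHL1 has a log2 ratio of -2.18 in shUCHL1 and -0.26 in shHSPA8 (p = 0.111 there), and HSPA8 has 0.36 in shUCHL1 (p = 0.00353) and -0.67 in shHSPA8. The authors' deposited table holds 2729, 2244 and 3495 genes with p under 0.05 for shUCHL1 against shCON, shHSPA8 against shCON and the knockdown lines against each other. Of the genes called here, 1873 of 1987, 1757 of 1859 and 1772 of 1843 also have p under 0.05 in the authors' deposited table, and every called gene has the same sign there.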

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

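All tests of explanations in this part were chosen after the results they bear on were seen. Of the genes called in both knockdown lines, 36 moved in opposite directions against shCON. All 36 passed the direct test between the knockdown lines, which calls of opposite sign make nearly certain, so that test adds no further evidence. WNT4, VGF and C23H6orf132 are among those that kept both calls with any 1 library left out.

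The first pattern is that 851 genes changed in the same direction in both knockdown lines. Chance values of the shared shCON libraries would give a covariance of the fold changes near that from the spread between those libraries, and the observed covariance exceeded it by 0.211, more than its leave-one-out SE of 0.0863. A trend with transcript length would lose the calls once removed, and 830 of the 851 (97.53%) kept them after the length correction. Fold changes of shHSPA8 against shCON had almost no trend with length (Spearman's rho -0.007), so few calls could be lost. The correction also raised the same-direction calls to 1217. The near absence of the trend there argues against length, and the kept calls add little. A shCON line that itself departed from the other lines cannot be told apart from a shared response, since there is no second control line: 25.9% of the 851 genes also differed between the knockdown lines, between the bounds of 5% and 50% set for this test. A general response of these cells to lowering either gene is a biological explanation that stays open, as a hypothesis, and other explanations were not tested.

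The second pattern is that contractile genes were lower in shUCHL1: in a list of 13 drawn up after the data were seen, 10 fell and none rose, with a median log2 fold change of -1.30, against 1 up and 1 down in shHSPA8. Fewer mesenchymal cells in the shUCHL1 cultures would lower abundant mesenchymal genes alike. Abundant mesenchymal genes, 20 in number, had a median of 0.0915, which lay 1.39 (SE 0.40) above the contractile median. The mesenchymal median also lay above 99.77% of 10000 random lists matched on expression. COL3A1 (10136 CPM in shUCHL1), DCN, LUM and P4HA1 were up, and FN1 (5237 CPM), THY1 and VIM were down. As a set, these 20 genes argue against an even loss of mesenchymal cells, though FN1, THY1 and VIM fell. The bound set for this test also asked that 5 of the 20 rise, and 4 did, so the explanation is not excluded. A looser bound, tried after the value was seen, was withdrawn. A loss of a contractile subset of the cells is not tested by these genes. Lower activity of the SRF and MRTF factors, or of YAP and TEAD, may underlie the fall as a biological hypothesis, and the tests of their target genes stand among the other observations.

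The third pattern is the rise of HSPA8 in shUCHL1. Scaling of the libraries would bring its log2 fold change near 0, and the lowest value over 4 scalings was 0.36 (SE 0.07, DESeq2 size factors). Against the TMM scaling, the other scalings moved the median of all genes by only -0.018 to 0.078. That is too little to bring 0.38 near 0, so a larger scaling difference is not excluded. Reads of other HSP70 genes counted for HSPA8 cannot be told apart from its own without the reads: 3 other HSP70 genes summed to 284 CPM in shUCHL1, 23.0% of the 1234 CPM that HSPA8 gained and above the bound of 10% set for excluding them. They stood at 161 CPM in shCON, so their own counted rise was 123 CPM (9.98% of the gain), though what share of their reads went to HSPA8 is not known. A joint rise of heat shock factor targets stays open as a biological hypothesis, with its test among the other observations.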

How the results depend on the processing

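The length correction, of gene and list tests, and the voom weights per group were chosen after seeing the data, and the other alternatives were planned. The counts of changed genes given next are for shUCHL1 against shCON, shHSPA8 against shCON and shUCHL1 against shHSPA8, in that order, followed by genes changed the same way and in opposite ways, where main counts are 1987, 1859, 1843, 851 and 36. A minimum absolute log2 fold change of 1 gave 794, 766, 581, 355 and 7, and an adjusted p under 0.01 gave 791, 824, 591, 354 and 7, both stricter by construction. Fitting only the 2 groups compared gave 1104 in shHSPA8, 3116 between the knockdown lines and 20 opposite. The voom weights gave 1132, 3456 and 20 for the same results. The length correction gave 2893 between the knockdown lines and 101 opposite, and brought UCHL1 in shHSPA8 to a call (log2 fold change -0.28). Why the length correction changed these results was not tested. Replicate number as a block gave 1230, 1131, 923, 512 and 14, and HSPA8 in shUCHL1 kept 0.38 with an adjusted p of 0.055 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (0.0013 to 0.175 over all alternatives). The numbers do not pair the libraries consistently. Deviations of same-numbered libraries correlated at 0.234 for shCON with shUCHL1, -0.537 for shCON with shHSPA8 and -0.225 for shUCHL1 with shHSPA8. With 2 libraries per line, -0.537 means that shCON 1 deviated like shHSPA8 2, and shCON 2 like shHSPA8 1. Their differences also ran opposite ways along transcript length (Spearman's rho 0.465 in shCON and -0.466 in shHSPA8). A block on replicate number cannot model an axis that crosses the numbers, and its source was not tested.

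Leaving out 1 library, with the lone library of a line assumed to vary like the others, gave 528 to 2615 changed genes in shUCHL1, 920 to 2416 in shHSPA8 and 257 to 3083 between the knockdown lines, 313 to 989 in the same and 8 to 42 in opposite directions. HSPA8 in shUCHL1 ran from 0.34 to 0.40 on the log2 scale and lost its call without either shUCHL1 library. Lists called fell from 16, 12 and 7 to 2, 4 and 1 with an estimated correlation, and between the knockdown lines fry called 13. The difference between the knockdown lines changed sign for genes near 0: TLR2 (0.0939 with library size alone), EDN1 (-0.0659 and -3.58e-04 without shUCHL1 replicate 2 and shHSPA8 replicate 2, 0.123 without shUCHL1 replicate 1) and GABRA4 (0.0534 without shHSPA8 replicate 2, -0.372 without replicate 1). The ribosomal list in shUCHL1 had medians of -0.298 and 0.0248 without shCON replicate 1 and 2. DESeq2, limma-voom, DESeq2 size factors, library size alone and both filter alternatives kept the number of changed genes in each comparison, and of genes changed the same way or in opposite ways, within 1.5 times. With library size alone the split by direction moved more, to 1339 genes higher in shUCHL1 than in shHSPA8 against 785, as the all-gene median shifted by 0.10. UCHL1 in shUCHL1 and HSPA8 in shHSPA8 kept their calls at an adjusted p under 0.05 in every fit, while HSPA8 (-0.66) lies under a minimum absolute log2 fold change of 1. Depth limits genes with few counts, such as PXDN in shUCHL1. Over both shCON libraries, COL18A1, IL1B and NRG1 had 15 counts each, MMP1 had 17 and MMP12 had 11. DES had 15 counts over both shUCHL1 libraries.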

Other observations

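Tests of transcription factor targets in this part were chosen after the contractile and HSPA8 results were seen, and the epithelial list was fixed earlier. Epithelial keratins and junction genes moved apart in shUCHL1: of 9 tested, 6 rose and 3 fell, and the list was not called (camera adjusted p = 0.932). KRT8 (log2 fold change -3.92, SE 0.22), its partner keratin KRT18 (-3.37, SE 0.47, with 12 counts over both shUCHL1 libraries) and plakoglobin JUP (-1.28, SE 0.15) fell, while the desmosomal plaque gene DSP rose (3.27, SE 0.33). KRT8, KRT18 and JUP also fell in shHSPA8 (-1.73, -2.31 and -1.26), where DSP was at 0.88 (SE 0.43) and did not pass the test.

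Annotated KEGG pathways from the deposited table gave groups beyond the fixed lists. Disease pathways and global maps were left out, and 238 of the others had at least 10 tested genes. Camera called 16, 21 and 11 of these 238 in shUCHL1, in shHSPA8 and between the knockdown lines, and 0 with an estimated correlation in each. The pathways named next bear on the contractile genes, and no fixed rule chose them. Between the knockdown lines, Vascular smooth muscle contraction had 24 of 82 genes lower and 5 higher in shUCHL1 (adjusted p = 0.00471 in camera) and Focal adhesion 39 of 165 lower and 9 higher (adjusted p = 0.0113 in camera), both with an adjusted p of 0.960 with an estimated correlation.

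A hypothesis from the fall of contractile genes is lower activity of SRF and its MRTF co-activators, which drive such genes. Outside the contractile list, 14 of 23 SRF and MRTF target genes fell in shUCHL1 and none rose, with a median log2 fold change of -0.48, below all of 10000 random lists matched on expression. In shHSPA8 the same targets had a median of -0.23 with 1 up and 5 down, above only 0.04% of the random lists. A second candidate is YAP and TEAD, whose targets had a median of -0.42 in shUCHL1 (1 of 20 up and 10 down, below all of 10000 random lists), with CTGF (-1.25), CYR61 (-0.96) and ANKRD1 (-2.12) lower. The YAP and TEAD targets had a median of -0.33 in shHSPA8 (6 down and none up, below all random lists). Both target sets thus lay lower in shHSPA8 too, where contractile genes did not fall as a group (1 of 13 up and 1 down). So the data may fit either factor pair and do not separate them.

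A hypothesis for HSPA8 in shUCHL1 is a rise of heat shock factor targets as a group. The other 18 HSF1 target chaperones had a median log2 fold change of 0.13 in shUCHL1, with 4 up and none down, above 99.78% of 10000 random lists matched on expression. Their median was 0.28 in shHSPA8, with 7 up and above 99.98% of the random lists, where HSPA8 itself was lowered by its hairpin. Random lists take no account of correlation between members, here or for the other target sets. All 18 are also in fixed lists, and the heat shock chaperone list lost its call with an estimated correlation (adjusted p = 0.433 in shUCHL1 and 0.401 in shHSPA8). The shift is small, and whether it may account for the 1.30-fold rise of HSPA8 was not tested.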
